A study of Mus musculus with 6 samples.

How the data were processed

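Total RNA from superior cervical ganglia of mice at postnatal day 0 on a mixed strain background was amplified to biotin-labelled cRNA and hybridised to Illumina mouse bead arrays, 1 array per sample. The 6 samples were assigned to 2 groups of 3 by the genotype in their labels, Egr3-null and wild type for Egr3, all lacking Bax. The arrays were processed in BeadStudio 3.1, per the submitters' processing notes.

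A pair of tables covered all 6 arrays. The deposited table used as the starting point held linear probe intensity with a detection p-value per probe and array. It had been named as not normalized, but its sorted intensities differed between arrays by at most 0.841% at any rank, with a minimum of 22.1 and a maximum of 24599.9 on every array and medians of 44.0, so the deposited intensities had already been quantile-normalized and had not been background-subtracted. The deposited detection p-value columns shared a header, and each was taken to belong to the intensity column before it, since p fell with intensity without exception for that pairing and with at least 15005 exceptions for any other. The second deposited table held linear intensity on a background-subtracted scale, with a mean of 158.8 on every array, between 27.4% and 29.5% negative values and medians between 5.60 and 6.18. It ranked the probes of each array exactly as the first table did, and how its scaling was made is not given in the sources used here. Values of 11 probe identifiers that occurred more than once were averaged.

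Intensities were background-corrected and normalized with neqc in limma 3.58.1 under R 4.3.3. This fits a normal-exponential model whose background is estimated from the detection p-values, adds an offset of 16 and applies quantile normalization and log2. Because the starting values had been quantile-normalized before, array effects that this step removed can no longer be seen. Of 46632 probes, 18538 to 19219 per array (39.8% to 41.2%) had a detection p under 0.01, and 19012 probes that did so on at least 3 of the 6 arrays were tested. Pairwise correlations of the arrays over the gene-level values described below were between 0.964 and 0.987. The first principal component of the same values held 41.6% of the variance and set wild-type sample 2 apart from the other samples. Probe names came from the platform annotation, which gave a single gene for 29976 probes and several for 10, with 16646 probes unnamed here. Of the probes with a single gene, 29921 matched a mouse reference gene table by gene identifier. That table served for names and, through its start positions, for which genes lie nearest to each other. Coordinates of the array annotation were not used because its build is not given in the sources used here. Of the tested probes 4577 were unnamed, and 0 of them passed. The probe with the highest mean over all 6 arrays stood for a gene, which gave 10088 genes, 3168 of them with more than 1 tested probe. Where a gene named for its difference between genotypes had other tested probes, 11 genes with 13 such probes, each of these showed under 0.5 times the difference of the probe that stood for the gene, and 6 had the opposite sign.

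The difference between genotypes was estimated with lmFit and eBayes of limma on the 6 arrays, with genotype as the only term, and is given as Egr3-null minus wild type on the log2 scale. P-values are two-sided and were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. An exact permutation test of 3 against 3 samples cannot give a two-sided p under 0.1, so none is reported for single genes. A gene whose probe was not above background on any array of a group has only a bound. It is given as the mean of the bright group over the mean, per array of the other group, of the higher of the probe's own value and the lowest value among detected probes. Simulations added known differences to 200 of 10088 unchanged genes, 50 per size, with 3 and 3 arrays and 5 repeats. The noise was independent between genes, and the 28 genes of a list were also raised by 0.5. Of genes changed by 0.5 on the log2 scale 12% were called, as were 93.2% at 1, 98.8% at 1.5 and 98.4% at 2. Of the calls 4.84% were false. So many changed genes loosen the adjusted threshold. In the data B3galt6 and Egr3 alone passed, and Nf1, at a log2 difference of 1.02, had an adjusted p of 0.395. The simulated shares therefore do not give the power of the real comparison.

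The 28 gene lists were fixed before the data were examined, as were the genes to be named, the design and most alternatives. The 23 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 over the gene-level values, adjusted over the lists. Single members were also adjusted over their list alone, a looser threshold without correction for the number of lists. Camera asks whether a list shifts relative to the other genes. It was repeated with the correlation estimated from the data, where 0 lists passed (lowest adjusted p = 0.955), and fry was run beside it, where 0 lists passed for movement on balance in 1 direction (lowest adjusted p = 0.868). The sign of the list's median was that of its test in every tested list, and that of its mean differed in 1, the neuronal ion channels. Named genes were Egr3 and Bax, up to 15 passing genes per direction filled up by unadjusted p to 10 where fewer passed, passing members of each list, the 4 members of lowest p of each list that shifted, and a few single genes, of which Th, Dbh, Ngfr, Egr1, Egr2, Egr4 and Arc are reported here. Ret, Cdc42se1, Mvd, Lss, Kcnk2, Hand2, Phox2a, Sox10, Lum, Acta1, Mcm6, Myh2, Ttn, C1qtnf12, Klhl17, Atad3a, Dmtn, Reep4 and Loxl2 were named after their values were seen. Medians are given for 7 of the lists, and for the others counts and the test alone, with a direction for the macrophage and erythroid lists in those fits where they passed, a restriction made after seeing that many lists that were not called changed sign between settings.

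Other settings, chosen beforehand, were no background correction with a floor of 16, median centring in place of quantile normalization, log2 of the second deposited table, no detection filter, detection on all 6 arrays, a detection p under 0.05, an offset of 50, the replicate number as a block, array weights, a variance prior with trend and robust estimation, the mean of a gene's detected probes, a threshold of 0.1 and leaving out each sample in turn. Before log2 of the second deposited table, low and negative values were raised to a floor and an offset of 16 was added. Added after seeing the data were a term for the sex pattern of Xist and Kdm5d, the mean of the skeletal muscle list as a covariate, neqc on the second deposited table, and the proliferation list without Mcm6.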

Results

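Transcript levels were measured in the superior cervical ganglion, the uppermost ganglion of the sympathetic chain, of newborn mice at postnatal day 0. One group of 3 samples lacked Egr3 and the other group of 3 samples was wild type for Egr3, and all 6 samples lacked Bax. Egr3 encodes a zinc finger transcription factor that is induced by extracellular signals such as nerve growth factor. Bax is a pro-apoptotic gene, and sympathetic neurons that lack it survive without trophic support. The comparison asked which transcripts of these ganglia depend on Egr3. Each sample was hybridised to a single-colour Illumina bead array, and between 18538 and 19219 of the 46632 probes per array were above background. After filtering, 10088 named genes were tested, with 3 arrays in each group, a number that limits the precision of every difference given here. The labels do not say whether the samples of a group came from separate animals, so the p-values measure the spread between these samples. On its brighter probe Xist was low in Egr3-null sample 2 (log2 intensity 4.68) and wild-type sample 1 (4.84) and lay between 9.06 and 10.08 in the other 4 samples. The Y-linked gene Kdm5d was at 5.63 in those same samples and between 4.15 and 4.24 in the other 4, so each genotype held 1 sample of that pattern.

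The deleted gene was lower in all 3 Egr3-null samples on the brighter of its probes. That probe (ILMN_1227494) had a normalized log2 intensity of 4.42 ± 0.22 (SD, n = 3) in Egr3-null ganglia and 5.93 ± 0.10 (SD, n = 3) in wild-type ganglia, a log2 difference of -1.51 (SE 0.15, limma adjusted p = 0.0277). It was not above background on any Egr3-null array and was above it on all 3 wild-type arrays, so the signal in wild-type ganglia was at least 2.24-fold higher. A second Egr3 probe (ILMN_2653543) stayed near background in both groups, at 4.83 ± 0.31 and 4.88 ± 0.16 (SD, n = 3 each), and did not separate them. It was above background on 2 of 3 arrays in each group and had its highest value, 5.15, in Egr3-null sample 1. Which part of the gene was deleted, and whether either probe lies in it, is not given in the sources used here. The adjusted p of Egr3 was 0.349 without Egr3-null sample 2, 0.314 without Egr3-null sample 3, 0.0658 without wild-type sample 2 and 0.191 without wild-type sample 3, at log2 differences between -1.64 and -1.45 over the 6 fits that left out a sample each. It also missed the threshold without background correction, without the detection filter, with the processed values of the authors and with a larger background offset. The same held for Egr3 with the mean over both probes, with skeletal muscle signal as a covariate and with the replicate number as a block. Bax had no named probe among those used and was not analysed here.

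In the fit to all 6 samples B3galt6 was the only gene that rose at an adjusted p under 0.05. It encodes a galactosyltransferase that builds the linker between core proteins and glycosaminoglycan chains of proteoglycans. Its brighter probe (ILMN_2687140) was at 6.72 ± 0.03 (SD, n = 3) in Egr3-null ganglia and 4.78 ± 0.07 (SD, n = 3) in wild-type ganglia, a log2 difference of 1.94 (SE 0.11, limma adjusted p = 0.00111) or 3.83-fold. The probe was above background on all 3 Egr3-null arrays and on 1 of 3 wild-type arrays. The second B3galt6 probe (ILMN_2488783) was above background on all 6 arrays and did not separate the groups, at 5.27 ± 0.06 and 5.27 ± 0.12 (SD, n = 3 each). The gene no longer passed with the mean of its probes (log2 difference 0.97, adjusted p = 0.145), and where a probe had to be detected on all 6 arrays the second probe stood for it (-0.0026). When each sample was left out in turn its log2 difference stayed between 1.90 and 1.97, past the threshold each time. With the replicate number as a block B3galt6 did not pass.

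**Figure D1:**
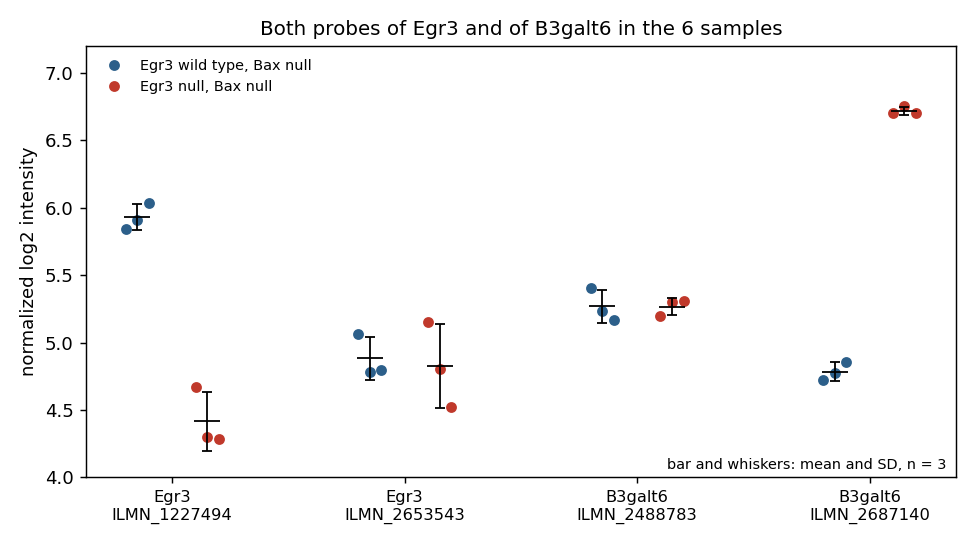
Normalized log2 intensity (vertical axis) of the Egr3 and B3galt6 probes in the 3 Egr3-null and 3 wild-type samples, each point being a sample and each bar with whiskers the mean and SD. The brighter Egr3 probe averages 4.42 against 5.93 and the probe that gave the B3galt6 difference 6.72 against 4.78, while the second probe of either gene overlaps between the groups.

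At an adjusted p under 0.05, 1 gene was higher and 1 was lower in Egr3-null ganglia, and the same held for single probes. At an unadjusted p under 0.05 there were 486 higher and 493 lower genes, which together are 9.70% of those tested. The groups did not overlap for 1728 genes (17.1%, where chance gives 10%). The next lowest adjusted p was 0.395. Without wild-type sample 1, 4 genes were higher and 10 lower, the muscle genes Myh2 and Ttn among the latter, and no gene was lower in the fits without Egr3-null sample 2, Egr3-null sample 3, wild-type sample 2 or wild-type sample 3.

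The genes named next by rank did not pass, and their adjusted p was 0.395. Among the point estimates above 0 were Nf1, the Ras GTPase-activating protein neurofibromin, at a log2 difference of 1.02 (SE 0.17), and Trp53inp1, a p53-induced nuclear protein, at 0.73 (SE 0.13). Mxra8, which encodes a cell surface immunoglobulin-domain protein, had a log2 difference of 1.05 (SE 0.20), and the junction protein gene Jup one of 0.76 (SE 0.14). The AP-1 subunit gene Jund was at 0.70, the sorting gene Tsg101 at 0.61, the amyloid precursor protein adaptor gene Apbb1 at 0.61, the ubiquitin ligase gene Trim2 at 0.56 and 1700093K21Rik at 0.78. Among those below 0 were Sox9, a transcription factor of chondrocytes and glial progenitors, at -0.89 (SE 0.16), and Insc, an adaptor of spindle orientation, at -0.999 (SE 0.19). The condensin subunit gene Ncaph was at -0.67, the DNA sensor gene Cgas at -0.81, the ceramide-1-phosphate transfer gene Cptp at -0.90, the Wnt ligand gene Wnt9a at -0.59, the clock repressor gene Nr1d2 at -0.63, Rbbp9 at -0.67 and Rcc1l at -0.65. Each of these genes had 3 values in 1 group that lay above all 3 in the other. Genes picked by lowest p from the same samples nearly always do, so this adds no support. Jup, Mxra8, Apbb1, Trim2 and Rbbp9 had other tested probes, and each of these showed under 0.5 times the difference. The second probe gave -0.08 for Jup, 0.07 for Mxra8, -0.11 for Apbb1 and -0.09 for Rbbp9, and the 3 further Trim2 probes lay between -0.19 and 0.26. Insc passed without wild-type sample 1 (-1.21, adjusted p = 0.0318).

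**Figure D2:**
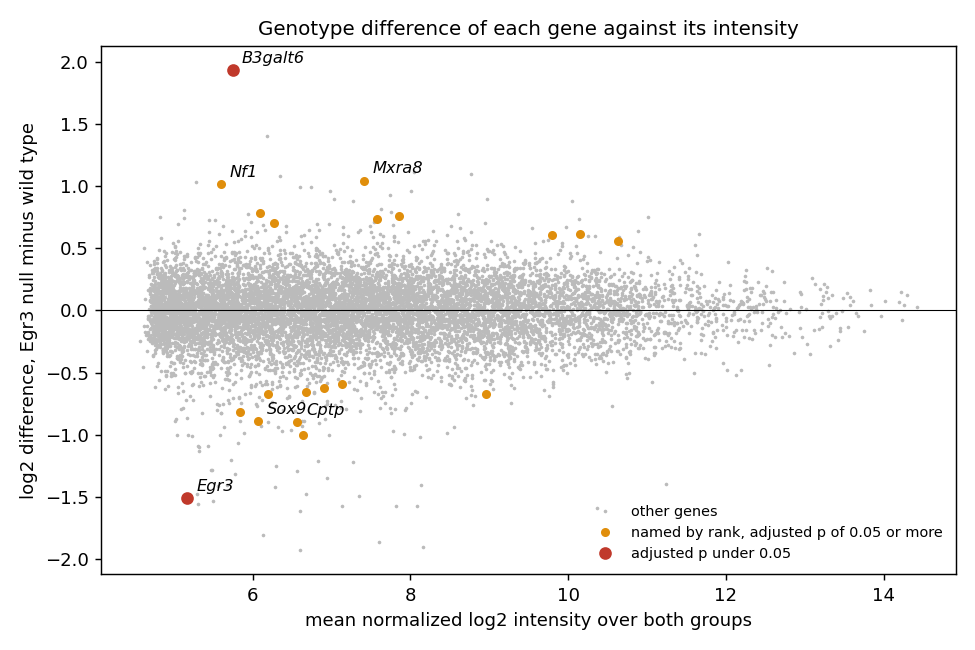
Log2 difference of each of the 10088 tested genes, Egr3-null minus wild type (vertical axis), against its mean normalized log2 intensity over both groups (horizontal axis), with 1 point per gene. B3galt6 at 1.94 and Egr3 at -1.51 are the genes with an adjusted p under 0.05, and the genes named by rank lie between -0.999 and 1.05.

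No measured gene of the sympathetic transmitter phenotype passed the test. Th, the rate-limiting enzyme of catecholamine synthesis, was at 10.89 ± 0.19 in Egr3-null and 10.88 ± 0.08 in wild-type ganglia (SD, n = 3 each), and the 95% confidence interval of its log2 difference ran from -0.31 to 0.32. Dbh, which converts dopamine to noradrenaline, was at 10.86 ± 0.06 and 10.74 ± 0.06 (SD, n = 3 each), with an interval from -0.14 to 0.38. Of the 24 measured genes of the noradrenergic list 0 passed, over all genes or adjusted over the list alone, and the list as a whole did not pass (median log2 difference 0.11, camera adjusted p = 0.143). It passed without wild-type sample 1 (0.18, adjusted p = 0.00325; adjusted p = 0.566 with an estimated correlation), and its median was -0.00038 without wild-type sample 2. The transcription factor genes Hand2 and Phox2a, chosen after their values were seen, were at log2 differences of 0.46 (SE 0.16) and 0.44 (SE 0.16), with adjusted p of 0.434 and 0.445. The chromaffin and carotid body list (11 measured, adjusted p = 0.290) and the list of neuropeptides and their receptors (13 measured, adjusted p = 0.819) held 0 genes that passed. Of the cholinergic list 3 genes were measured and 0 passed, too few for a test of the list.

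Genes of neurotrophin and GDNF signalling showed 0 members past the threshold over all genes among 12 measured, and 2 that passed when adjusted over the list alone. These were Ret, the signalling receptor of the GDNF family, at a log2 difference of -0.68 (SE 0.15, adjusted p over the list alone = 0.0239), and Cdc42se1 at -0.43 (SE 0.12, adjusted p over the list alone = 0.0426). Cdc42se1 was counted here as a member of the list, and its part in this signalling was not examined. Of the 6 fits that left out a sample, Ret passed over the list alone in 2, those without Egr3-null sample 3 or wild-type sample 1, and Cdc42se1 in 1, that without wild-type sample 1. Neither passed with the mean of the probes per gene, and the second probe of Ret gave -0.04 and that of Cdc42se1 gave 0.02. Ngfr, the low-affinity neurotrophin receptor p75, was at 10.47 ± 0.25 and 11.01 ± 0.24 (SD, n = 3 each), a log2 difference of -0.54 (SE 0.18, adjusted p = 0.420 over all genes). Ngfr missed the threshold over the list alone, but passed it without Egr3-null sample 3 and without wild-type sample 1. It also did so without background correction, with detection on all 6 arrays, with array weights, with the trend and robust prior and with an offset of 50. In the remaining settings it did not. The list median was -0.17 (camera adjusted p = 0.13), and without wild-type sample 1 it was -0.29 and passed (adjusted p = 0.0127; adjusted p = 0.566 with an estimated correlation). It was 0.0030 with skeletal muscle signal as a covariate.

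Egr1, a relative of Egr3 that was above background, was at 7.45 ± 0.36 in Egr3-null and 7.63 ± 0.57 in wild-type ganglia (SD, n = 3 each), and its interval ran from -0.86 to 0.49. The probes of Egr2 and Egr4 were not above background on any array. Of the EGR family and its cofactors 3 genes were measured and 0 passed. Arc, an activity-regulated gene, was at 4.78 ± 0.24 and 5.07 ± 0.10 (SD, n = 3 each, adjusted p = 0.556), and 0 of the 12 measured immediate early genes passed (list adjusted p = 0.900).

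Lists of genes for the outgrowth and wiring of neurons did not pass either. None of the 28 measured genes of dendrite morphogenesis passed, over all genes or over the list alone (camera adjusted p = 0.870), nor did any of the 36 genes of axon growth and guidance (adjusted p = 0.819) or of the 15 genes of neurofilaments and the cytoskeleton (adjusted p = 0.870). Of 18 neuronal ion channel genes 0 passed over all genes and 1 adjusted over the list alone, the tandem-pore potassium channel gene Kcnk2, at a log2 difference of -0.64 (SE 0.14, adjusted p over the list alone = 0.0263; list adjusted p = 0.870). Of 22 genes of nicotinic receptors and the synapse 0 passed, and the list did not pass as a whole (adjusted p = 0.908). The fry test for change in either direction gave an adjusted p of 0.0386 for this list and also 0.0386 for the list of cell death and p53 targets, and passed in these 2 of the 23 tested lists. In the cell death list 0 of 23 genes passed over all genes and 1, Trp53inp1, adjusted over the list alone (adjusted p over the list alone = 0.00827; camera adjusted p of the list = 0.290).

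Proliferation genes tended to lower point estimates in Egr3-null ganglia, and their shift was called at the preset correlation alone. Of 21 measured genes, 19 had point estimates below 0 and 2 above it, the median log2 difference was -0.39, and the list passed camera with the preset correlation (adjusted p = 0.000145). With the correlation estimated from the data, at 0.425, the call was lost (adjusted p = 0.955), as it was with fry (adjusted p = 0.868). The list median, centred on each gene's mean, was -0.09, -0.05 and -0.38 in Egr3-null samples 1, 2 and 3. It was 0.24, 0.55 and -0.16 in wild-type samples 1, 2 and 3, so wild-type sample 3 lay below Egr3-null samples 1 and 2. No single member passed, over all genes or over the list alone, whereas 8 passed over the list alone without wild-type sample 3. The mitotic kinase genes Aurka, Aurkb and Plk1 were at -0.62 (SE 0.18), -0.58 (SE 0.21) and -0.73 (SE 0.30), and the replication licensing gene Mcm5 at -0.47 (SE 0.20). Mcm6, a gene of the same complex named after its values were seen, was at -1.87 (SE 0.82) on a probe that was above background in 2 of 3 Egr3-null samples, and its second probe gave -0.50. Without wild-type sample 2, Aurkb was at -0.36, Plk1 at -0.45 and Mcm6 at -0.51. Without Mcm6 the list median was -0.38 (adjusted p = 0.000213). With an estimated correlation the adjusted p was 0.955 without Mcm6 and 0.930 without wild-type sample 2. The list median was -0.21 without wild-type sample 2 (adjusted p = 0.0195) and -0.23 with skeletal muscle signal as a covariate (adjusted p = 0.0190; adjusted p = 0.947 with an estimated correlation), and with array weights it was -0.13 and did not pass (adjusted p = 0.176). Skeletal muscle genes were lower in the same comparison, by a median of -1.40, and were highest in wild-type sample 2, which also had the highest proliferation median.

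Markers of the other cells of the ganglion were given the same test. Of 17 measured genes of satellite glia and Schwann cells 0 passed (list median -0.13, camera adjusted p = 0.0935), and Sox10, a transcription factor of glia chosen after its values were seen, was at -0.57 (SE 0.25, adjusted p = 0.514). Of 24 fibroblast and connective tissue genes 0 passed (list median -0.20, adjusted p = 0.0935), and Lum, a collagen-binding proteoglycan gene chosen likewise, was at -0.59 (SE 0.23, adjusted p = 0.472). Both lists passed without Egr3-null sample 1 (medians -0.20 and -0.24, adjusted p = 0.0187 and 0.0112), without wild-type sample 1 (-0.27 and -0.45, adjusted p = 0.000803 and 3.94e-07) and with the mean of the probes per gene (adjusted p = 0.0432 and 0.0435). With an estimated correlation the adjusted p was at least 0.566 in these fits. The fibroblast median was 0.082 with skeletal muscle signal as a covariate. Of 20 endothelial and pericyte genes 0 passed (list median 0.10, adjusted p = 0.290), and the median was -0.017 without wild-type sample 1. That list passed without Egr3-null sample 2 (0.26, adjusted p = 0.000969), without wild-type sample 2 (0.23, adjusted p = 0.0134) and with skeletal muscle signal as a covariate (adjusted p = 0.0190), with adjusted p of 0.834, 0.930 and 0.947 with an estimated correlation. The macrophage and immune list (17 measured, adjusted p = 0.900) and the erythroid list (6 measured, adjusted p = 0.870) held 0 genes that passed. Each passed as a list in 2 further fits, the former in opposite directions. The macrophage list passed as lower in Egr3-null ganglia without wild-type sample 1 (adjusted p = 0.0286; adjusted p = 0.701 with an estimated correlation) and as higher with skeletal muscle signal as a covariate (adjusted p = 0.0190; adjusted p = 0.947 with an estimated correlation). The erythroid list passed as higher without wild-type sample 2 (adjusted p = 0.0431; adjusted p = 0.930 with an estimated correlation) and with that covariate (adjusted p = 0.0443; adjusted p = 0.947 with an estimated correlation).

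Skeletal muscle genes, which mark tissue outside the ganglion, had the largest median difference of the lists tested. All 15 measured genes had point estimates below 0 in Egr3-null ganglia, with a median log2 difference of -1.40 (camera adjusted p = 0.000145), and the call was lost with an estimated correlation (adjusted p = 0.955) and with fry (adjusted p = 0.868). No single gene passed. The contractile and calcium-handling genes Actn3, Mybpc1, Pvalb and Myh8 were at -0.83 (SE 0.35), -1.48 (SE 0.70), -1.29 (SE 0.62) and -1.90 (SE 0.95), and without wild-type sample 2 at -0.36, -0.70, -0.62 and -0.91. Without wild-type sample 1 Mybpc1 was at -2.39, Pvalb at -2.09 and Myh8 at -3.09. The probes of Mybpc1 and Pvalb were above background on 1 of 3 Egr3-null and 2 of 3 wild-type arrays. The signal was uneven among the wild-type samples. The median of the list, centred on each gene's mean, was 2.30 in wild-type sample 2 and 0.94 in wild-type sample 3 but -1.25 in wild-type sample 1, against -0.97, -0.12 and -0.89 in the Egr3-null samples. Without wild-type sample 2 the median difference was -0.36 and the list no longer passed (adjusted p = 0.161), and without wild-type sample 1 it was -2.37.

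**Figure D3:**
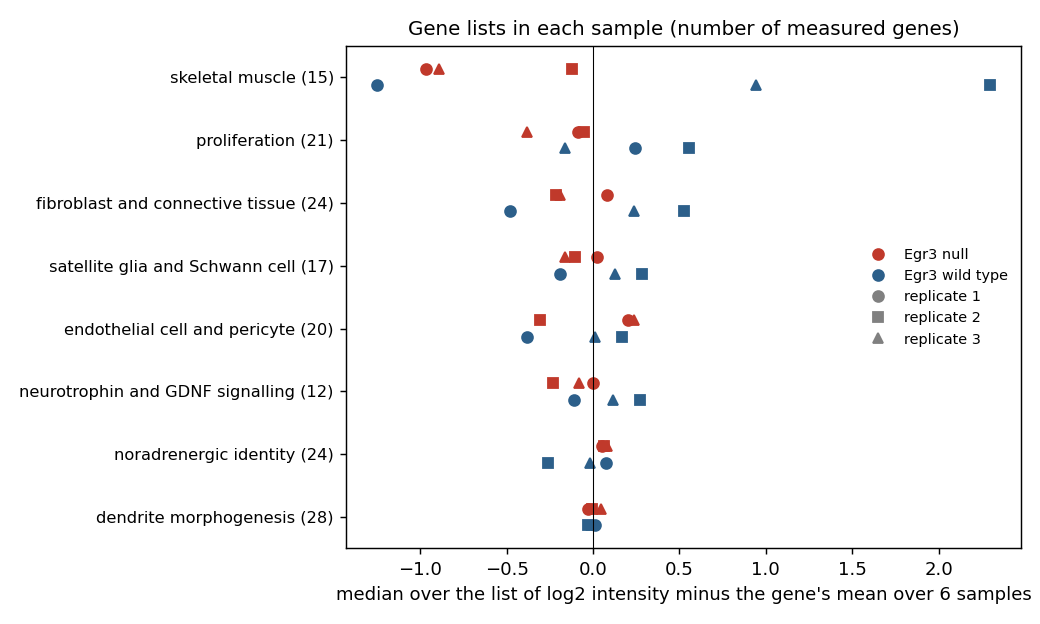
Median over each gene list of the log2 intensity minus the gene's mean over the 6 samples (horizontal axis) for 8 lists (rows, with the number of measured genes), each point being a sample. Skeletal muscle spans from -1.25 in wild-type sample 1 to 2.30 in wild-type sample 2, and the 3 Egr3-null samples lie between these values.

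The remaining lists held 0 genes that passed over all genes. Of 17 genes of cholesterol synthesis, 2 passed when adjusted over the list alone, the mevalonate pathway gene Mvd at a log2 difference of 0.62 (SE 0.15) and the lanosterol synthase gene Lss at 0.50 (SE 0.13), each with an adjusted p over the list alone of 0.0396. The second Lss probe gave -0.03. The cholesterol list as a whole had an adjusted p of 0.0935, and passed without Egr3-null sample 3 (adjusted p = 0.0324), without wild-type sample 1 (adjusted p = 0.00960) and with array weights (adjusted p = 0.0311), none of which held with an estimated correlation (adjusted p of 0.922, 0.599 and 0.795). Heat shock and hypoxia genes (19 measured, adjusted p = 0.978) and interferon response genes (14 measured, adjusted p = 0.870) did not pass. The sensory ganglion list (5 measured, adjusted p = 0.13) passed in 2 of the 6 fits that left out a sample, those without wild-type sample 1 (adjusted p = 0.0114) and wild-type sample 3 (adjusted p = 0.0394), again not with an estimated correlation (adjusted p of 0.566 and 0.956). The 24 measured genes of the list of Egr3 neighbours on chromosome 14 did not pass either (adjusted p = 0.321). The cartilage and bone list (4 measured), the sex-linked list (2 measured) and the list of thyroid, thymus and epithelium (1 measured) were too short to test, and Sox9 of the first passed adjusted over the list alone (0.00174). The adjustment over a list alone was not corrected for the 28 lists, and none of the genes that passed it passed over all genes. Over the 28 lists 7 genes passed adjusted over their list alone, a number that was 1 without Egr3-null sample 1, 2 without Egr3-null sample 2, 4 without wild-type sample 2, 10 without wild-type sample 3, 7 without Egr3-null sample 3 and 43 without wild-type sample 1. It was 22 with array weights, 5 of them skeletal muscle genes, and 3 with the mean of the probes per gene. Of the 6 fits that left out a sample, Sox9 passed in 6, Trp53inp1 in 5, Ret in 2 and Cdc42se1, Kcnk2, Mvd and Lss in 1 each.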

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

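The fits with a sex term, with the muscle covariate, with neqc on the second deposited table and without Mcm6 were chosen after the data were seen. The median difference over all genes stayed within 0.02 of 0 on the log2 scale in every setting. Median centring, the looser detection filter and neqc on the second deposited table kept both genes and both lists past the threshold. Where no cause is given below, the cause was not tested.

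Egr3 kept its direction but missed the threshold, leaving 0 lower genes and 0 lower probes, without background correction (log2 difference -1.02, adjusted p = 0.109), with log2 of the second deposited table (-1.67, adjusted p = 0.0521), without the detection filter (-1.51, adjusted p = 0.159; more genes were tested) and with an offset of 50 (-0.78, adjusted p = 0.145). Over all settings that kept the 6 samples its adjusted p ran from 0.0117 to 0.452. With detection on all 6 arrays 0 genes and 0 probes passed in either direction, because the Egr3 probe is then left out and the other B3galt6 probe stands for that gene (-0.0026, adjusted p = 0.996). With the mean of a gene's probes 0 genes passed in either direction, with B3galt6 at 0.97 (adjusted p = 0.145) and Egr3 at -0.79 (adjusted p = 0.452), since the second probes enter the mean, and 4 lists passed. Array weights gave 2 higher and 3 lower probes and took the proliferation list to -0.13 (adjusted p = 0.176). A prior with trend and robust estimation gave 2 higher and 2 lower probes, as did a threshold of 0.1. The sex term left 0 lower probes, with Egr3 still past the threshold at the gene level (adjusted p = 0.0462).

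With skeletal muscle signal as a covariate, 0 genes were lower, Egr3 was at -1.51 (adjusted p = 0.0885) and 4 lists passed, proliferation among them. The skeletal muscle list was then at 0.0044 and Acta1 at 0.17, by construction, the fibroblast list at 0.082, the neurotrophin list at 0.0030, Th at -0.021 and Egr1 at 0.012. Th was at -0.011 with the second deposited table. Camera with an estimated correlation passed 0 lists (adjusted p = 0.955 for both proliferation and skeletal muscle), and fry for movement on balance in 1 direction passed 0 (adjusted p = 0.868 for both), while fry for change in either direction passed 2 other lists.

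Same-numbered samples did not deviate together (correlations of -0.11, -0.07 and -0.01), so the numbers were not taken to pair the samples. With the replicate block 0 genes and 0 probes passed in either direction, with B3galt6 at 1.94 (adjusted p = 0.0665) and Egr3 at -1.51 (adjusted p = 0.318) on fewer residual degrees of freedom, 3 lists passed (proliferation, skeletal muscle and sensory ganglion, the last at adjusted p = 0.0181) and 3 genes passed over their list alone, 2 of them shared with the fit without the block. With an estimated correlation under that block, each of the 3 lists had an adjusted p of 0.935. No slide was given in the files used, so a slide block was not run.

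When each sample was left out in turn, 1 to 4 genes were higher and 0 to 10 lower, 1 to 8 probes were higher and 0 to 17 lower, and 3 to 9 lists passed. The highest counts came without wild-type sample 1. Egr3 lay between -1.64 and -1.45 (adjusted p from 0.0193 to 0.349), B3galt6 between 1.90 and 1.97 (adjusted p from 0.00252 to 0.024), the proliferation list between -0.54 and -0.21 and the skeletal muscle list between -2.37 and -0.36, the latter without wild-type sample 2. Of the values given with a direction, those that crossed 0 were Th (-0.090 to 0.097), Egr1 (-0.48 to 0.086), the endothelial list (-0.017 to 0.26) and the noradrenergic list (-0.00038 to 0.18). Over all settings, values of the other named genes kept their direction and side of the threshold 985 times, changed sign 7 times and came to pass 3 times (Insc, Myh2 and Ttn without wild-type sample 1). For the other lists given with a direction these numbers were 85, 4 and 11. Lists given without a direction stayed short of the threshold 309 times and passed 10 times, and changes of their sign were not counted. Signal over background limits the Egr3 comparison, whose probe is at background in Egr3-null ganglia, and Egr2 and Egr4, which were not above it.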

Other observations

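The counts of genes and lists with an adjusted p under 0.05 over other splits of the samples were set before the data were examined, and every other test in this part was chosen after the result it bears on was seen.

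Genes that lie next to the genes with the strongest differences were looked at because the mice were of mixed strain background. Of the 20 measured genes nearest to B3galt6 on chromosome 4, 5 had an unadjusted p under 0.05. Mxra8 (log2 difference 1.05), Klhl17 (0.78) and C1qtnf12 (0.63) were higher in Egr3-null ganglia, and Cptp (-0.90) and Atad3a (-0.50) were lower. Of the 20 nearest to Egr3 on chromosome 14, 3 had such a p, Dmtn at 0.48, Reep4 at -0.64 and Loxl2 at -0.55, and none of these genes passed after adjustment. Over all tested genes 9.70% had such a p.

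Of the 10 splits of the 6 samples into 3 and 3, the real one gave 2 genes, B3galt6 and Egr3, and each of the others 0. The deleted gene Egr3 differs by design in the real split, so its part in this count was fixed beforehand. At an unadjusted p under 0.05 the real split gave 979 genes and the highest of the others 886, with Egr3-null sample 1 beside wild-type samples 2 and 3. With 10 splits no share under 0.05 can be reached. As many lists as the real split's 2, or more, passed camera in 8 of the 10 splits, the real one among them. The highest count of another split was 10 lists, so the number of lists past camera at the preset correlation does not set the real split apart.

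B3galt6 was higher on 1 of its probes alone. A sequence or transcript difference under that probe may be the reason, since the second probe differed by -0.0026 where the first differed by 1.94, a result that a change of the whole transcript pool would not give unless the second probe fails to report it. A stretch of other strain origin around the gene stays open, since the mean absolute t of the nearest 20 genes was matched by 0.444% of all such windows when Cptp and Mxra8, known to stand out beforehand, were counted, and by 13.7% without them. Around Egr3 itself the same measure, chosen after the data were seen, was matched by 3.76% of windows. The list of Egr3 neighbours fixed beforehand did not pass camera (adjusted p = 0.321) or fry for change in either direction (adjusted p = 0.219). Strain sequence carried along with the deleted allele therefore stays open. Neither a transcript difference nor an effect of Egr3 on B3galt6 was tested directly, and the array probes were not placed on a sequence.

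Skeletal muscle signal differed widely between single samples. All 15 measured muscle genes were highest in wild-type sample 2, and Acta1, an abundant muscle transcript, reached 13.56 there and 11.32 in wild-type sample 3 against 8.61 in wild-type sample 1 and 9.19, 10.45 and 9.07 in the Egr3-null samples. Muscle carried along in the dissection of single samples is a candidate explanation that these values meet. The 15 genes moved together (estimated correlation 0.93), so a shared highest sample does not tell this explanation from others. The values argue against a difference shared by every wild-type sample, since wild-type sample 1 lay above the Egr3-null mean for 1 of the 15 genes. Of these 15 genes 1 is also in another list and 11 were above background on all 6 arrays, and an effect of genotype on muscle next to the ganglion was not tested.

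The proliferation list was lower in Egr3-null ganglia at a preset correlation alone, and 3 accounts of this were left open. Genes of a single programme deviate together, and 2 of the 10 splits, the real one among them, gave a list mean difference as large as the real -0.42. The highest of the others was 0.50, and 10 splits cannot give a share under 0.05. Without Mcm6 the real difference was -0.35, and 3 splits, again with the real one among them, gave one as large. Cells that came along with muscle may contribute. Wild-type sample 3, with more muscle signal, had a median difference of -0.38 from wild-type sample 1, with 15 of 21 genes lower (exact two-sided sign test p = 0.0784). That test compares single samples and counts genes as independent, though their estimated correlation was 0.425, so it cannot decide. With muscle signal as a covariate the list median was -0.23. Camera then gave an adjusted p of 0.0190 at the preset correlation and 0.947 with an estimated correlation, so this fit does not decide either. A lower share of all non-neuronal cells would lower endothelial genes alike, and their list mean difference lay 0.54 (SE 0.27) above that of the proliferation list, which is within 2 standard errors (0.47, SE 0.31, without Mcm6). The endothelial list alone was compared in this way. Point estimates were below 0 for 13 of 17 genes of satellite glia and Schwann cells and 19 of 24 fibroblast genes. They were above 0 for 15 of 20 endothelial, 9 of 17 macrophage and 4 of 6 erythroid genes. An effect of genotype on these genes stays open and was not tested.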
